A study of Mus musculus with 8 samples.

How the data were processed

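Total RNA of mouse skin was extracted with Trizol, depleted of ribosomal RNA and made into stranded libraries, per the labels' protocols. The 8 libraries fall into 2 groups of 4: skin from areas that had received 35 Gy of electrons 24 h earlier, and skin from areas left out of the beam. The labels give each library a replicate number. They do not state that each library came from a separate mouse or that equal numbers mark the same mouse, so the p-values measure the spread between these libraries, part of which may be technical.

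The deposited table holds 22565 rows, of which 1 was empty and was left out, and 22564 protein-coding genes with Ensembl identifiers. The FPKM values (fragments per kilobase of transcript scaled to the mapped fragments of the library) were deposited by the authors, per the file headers. The same table holds deposited estimated counts per gene and library, per the file headers. cutadapt 1.9.3, HISAT2 2.0.4, Cufflinks, Cuffdiff and the genome build mm10 are named in the submitters' processing notes, with no role or order. The tool that wrote the table, the annotation release and the use of strand in counting are not given in the sources used here. For 57.46% of the 6747 genes with over 20 counts in every library, the FPKM value per count varied between libraries with an SD over 0.1 on the log2 scale. Gene coordinates come from GENCODE M21, on the same assembly as mm10, matched by gene identifier, which found 96.79% of the identifiers. The spans in the table often merge neighbouring genes and were not used for coordinates.

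The deposited estimated counts of a library are mostly whole multiples of 1 step, which lies between 0.871 and 1.1 and differs between libraries. Division by that step gave values within 0.02 of a whole number for between 92.55% and 96.25% of the genes of a library, counted among values below 2000 steps. These recovered reads total between 5036273 and 6626647 per library. Within the range searched, genes with few reads pile up at a read count typical of the library. That peak was located between 3.5 and 300 reads with a smoothing width of 0.15 on the natural log scale, and is called here the commonest low read count. A peak at 1 read lay outside this range and could not be found. The peaks of nonirradiated replicates 2 and 3, at 4.47 and 4.78 reads, lay near its lower edge. Recovered reads divided by the commonest low read count and rounded are called units. They stand in for distinct fragments only as an assumption, and intervals or floors taken from them cover counting error only.

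The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a mean-variance trend and robust moderation, irradiated minus nonirradiated, on the 13324 genes with a mean of at least 0.5 FPKM over the 8 libraries. P-values were adjusted over these genes by the Benjamini-Hochberg method, with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Because the deposited counts are scaled and partly fractional, no raw counts were tested, and FPKM stayed the main unit as planned. The 35 gene lists were tested with camera at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry. Adjustment for the lists was over the 35 lists. Members were also counted after adjustment over the list alone. A gene symbol found in several rows was represented by the row with the highest mean. Each list mean was also set against 10000 random lists matched on mean expression in 20 bins. For hair shaft, mitosis and histone genes this was repeated, after seeing the data, with each bin split into 5 by units. Values of whole libraries were compared with exact two-sided permutation tests, whose smallest possible p with 4 against 4 libraries is 0.0286.

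The lists, the tests and the rule for named genes were fixed before the data were examined. The rule takes the 10 largest rises and the 10 largest falls among called genes whose groups do not overlap and whose higher group has a mean of at least 1 FPKM, without predicted genes and clones. It adds up to 4 members of each list by smallest p, here 4 of each called list and 1 of each other list, a number set after the fit was seen. It always takes Cdkn1a, Mdm2, Bax, Trp53, Mki67, Krt14, Krt10, Il6, Il1b, Fabp4, Ppara and Adipoq. Of the 98 genes it named, 11 overlap another gene of the table in the annotation, so their values are uncertain. Dbp, Far2, Hirip3, Lig3, Mb, Rfc4, Srebf1, mt-Nd5 and mt-Nd6 overlap a gene on the opposite strand, whose reads cannot be told apart from theirs without strand. mt-Nd4 overlaps mt-Nd4l by 7 bp on the same strand. Egfl7 overlaps Gm20532 by 6482 bp on the same strand and Agpat2 by 64 bp on the opposite strand. Replication-dependent histone genes and keratin genes have near-identical copies, so their values are uncertain where reads were shared.

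Other settings fixed in advance were another pseudocount, 2 other filters, median ratio scaling, quantile normalization, array weights, a fit with no trend or robust moderation, a replicate block, each library left out in turn and a minimum log2 change of 1. Settings chosen after seeing the data were edgeR 4.0.16 with its quasi-likelihood test and DESeq2 1.42.0 on the recovered reads rounded to whole numbers, edgeR on units and on units thinned to the 75894 of the smallest library, the fit without irradiated replicates 1 and 4, and the skeletal muscle index as a covariate. DESeq2 ran on genes with at least 10 reads in at least 4 libraries. It gave no adjusted p for 207 genes, which stayed out of its counts.

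The main test was tested on simulated data drawn with the unit numbers of the real libraries and a dispersion of 0.0369, with 100 genes changed 2-fold and 100 changed 4-fold in each of 20 datasets, all from a mean of 5 FPKM up. For irradiated against nonirradiated libraries, limma on a mean of 13110 genes called 6.6% of the 2-fold and 50.5% of the 4-fold genes. On average 24.7 of its calls, 30.0% of them, were unchanged genes, and 24.4 of these were called lower in the irradiated libraries. So the adjusted p of limma did not hold its nominal rate in this simulation, on the side of lower genes. With no gene changed it called 1.1 genes per dataset, and 882 genes lay at an unadjusted p under 0.05, 79.6% of them lower. edgeR on simulated units, in 5 datasets and a mean of 5815 genes, called 33.4 of the 2-fold and 69.6 of the 4-fold genes with 3.4 false calls. Camera called 0.2 of the 35 lists per dataset with no change. The simulated genes were drawn independently of each other, so this does not check camera where the genes of a list vary together. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.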

Results

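The transcriptome of mouse skin was compared between areas collected 24 h after a single dose of 35 Gy of electrons and nonirradiated areas, with 4 libraries in each group. Recovered reads came to 6065250 ± 540382 (SD, n = 4) in irradiated and 5764980 ± 528342 (SD, n = 4) in nonirradiated libraries. A value above 0 was listed for 11113.5 ± 1582.5 genes (SD, n = 4) in irradiated and 13840.5 ± 936 (SD, n = 4) in nonirradiated libraries (exact two-sided permutation p = 0.0571, adjusted p = 0.0980 over 12 measures). The commonest low read count was 51.5 ± 28.6 reads (SD, n = 4) in irradiated and 9.94 ± 6.14 (SD, n = 4) in nonirradiated libraries, with no overlap (exact permutation p = 0.0286, the smallest this design allows, adjusted p = 0.0686). Pairs of irradiated libraries correlated at 0.65 to 0.79 across genes and pairs of nonirradiated libraries at 0.83 to 0.93; genes are not independent replicates.

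**Figure D1:**
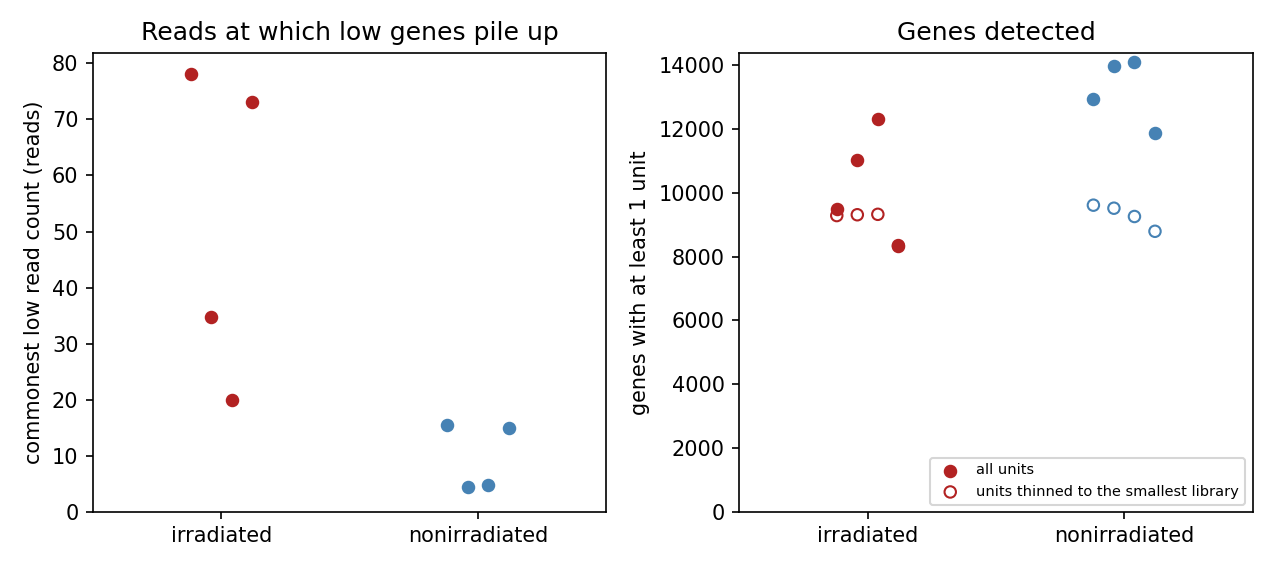
Left, the commonest low read count (reads, vertical axis) of each library, 1 point per library, for 4 irradiated (red) and 4 nonirradiated (blue) libraries. Right, genes with at least 1 unit in each library, with all units (filled) and after thinning to 75894 units (open); the means of 10291 and 13212 genes become 9064 and 9292.

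The question put to the data was which genes differ between irradiated and nonirradiated skin. Irradiated skin had more RNA of Elovl4, which lengthens very long chain fatty acids, at 398 ± 76.2 against 61.6 ± 17.0 FPKM (SD, n = 4 each). Ccng1, a target gene of p53, rose from 62.0 ± 10.9 to 208 ± 16.2 FPKM (SD, n = 4 each). Mki67, a marker of dividing cells, fell from 96.6 ± 13.5 to 22.6 ± 6.14 FPKM, and Krt28, a keratin of the inner root sheath of the hair, fell from 83.5 ± 12.8 to 10.5 ± 5.25 FPKM (SD, n = 4 each). In limma, 33 of 13324 genes passed the adjusted threshold of 0.05, of which 16 were higher and 17 lower in irradiated skin. At an unadjusted p under 0.05 there were 1718 genes, 757 higher and 961 lower. The nominal rate gives 666, and data simulated with these unit numbers and no change gave 882 on average, 79.6% of them lower.

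Elovl4 (ENSMUSG00000032262, chromosome 9, 83778692 to 83806277) had a log2 change of 2.69 with an SE of 0.25 and a limma adjusted p of 0.00651. S100a8 (chromosome 3, 90668978 to 90670035), which encodes a subunit of the alarmin calprotectin, had a log2 change of 4.84 with an SE of 0.50. Its 4 irradiated libraries averaged 68.1 ± 19.9 FPKM (SD, n = 4) against 1.71 ± 1.55 (SD, n = 4), from 15 and 1 units in all. Far2, a fatty acyl reductase, rose by 2.52 and Sdr16c6, a member of the short-chain dehydrogenase family, by 2.47. The other called rises with the largest changes were genes of striated muscle: Ankrd1 (4.40), Myl4 (3.76), Myh1 (3.37), Myoz2 (3.09), Xirp2 (2.69) and Lmod2 (2.10). The remaining called rises were Ccng1, Serpinb2, Spink5, Nexn, Tmem182 and Gm10053.

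Among the largest called falls, Krt28 (chromosome 11, 99364872 to 99374903) had a log2 change of -2.97 with an SE of 0.34 and an adjusted p of 0.00870 in limma. The other 9 had from 11 to 92 units in the nonirradiated libraries together, with fitted changes from -4.34 to -2.69. They were Edf1, Hist1h2bn, Snrpe, Mt4, Atat1, Hirip3, Mlana, Hist2h3b and Mrps33. Of these, Snrpe, Mlana, Mt4 and Hist2h3b were listed at 0 in every irradiated library. Against a floor of 3 units for the irradiated group, the nonirradiated rate of Snrpe was 1.83 times the floor, from 27 units. That of Mlana, a melanocyte gene, was 1.43 times the floor, from 21 units. This ratio is used below as the bound of a gene listed at 0 throughout a group. It leaves out the counting error of the units in the other group, so it is not a lower limit of the change. Mt4 and Hist2h3b had 12 and 11 units in nonirradiated libraries, below what that floor could show. In all, 10 of the 17 lower genes had under 10 units in the 4 irradiated libraries together, and edgeR on units could test 7 of the 17, all of which it called lower. It tested 13 of the 16 higher genes and called all 13. Genes that every cell uses were also listed at 0: of 92 ribosomal protein and small nuclear ribonucleoprotein genes, between 3 and 24 per irradiated library and between 1 and 4 per nonirradiated library.

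**Figure D2:**
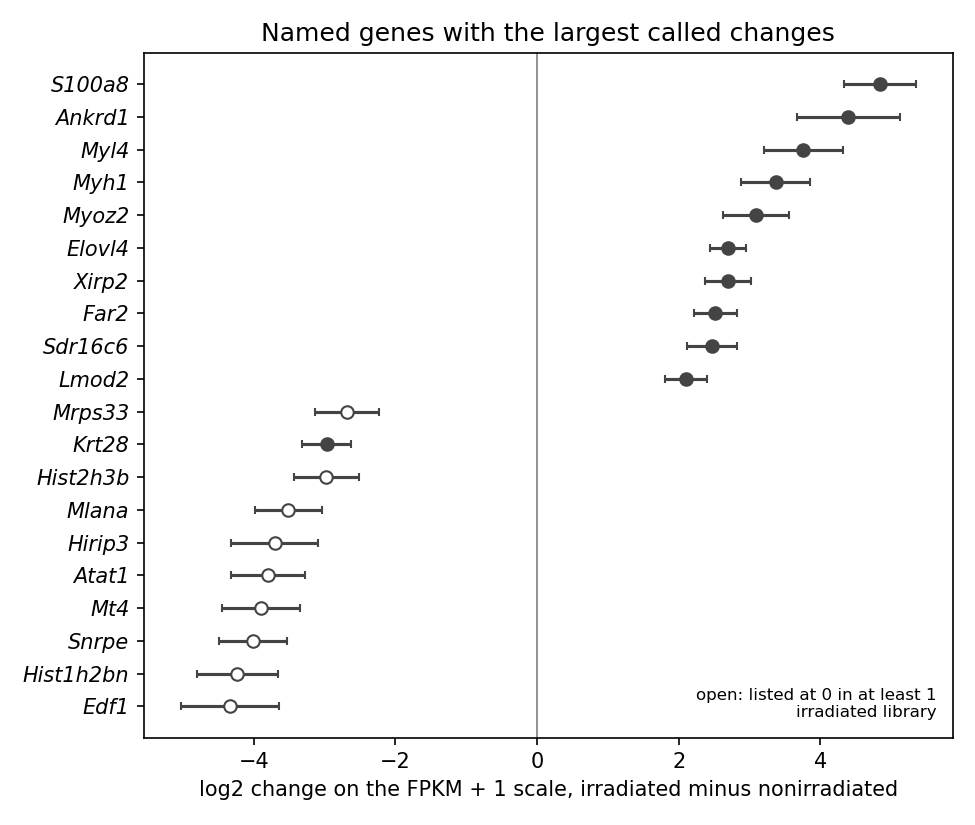
Log2 change on the FPKM + 1 scale (horizontal axis, irradiated minus nonirradiated, 4 libraries each) of the 10 largest rises and 10 largest falls named by the fixed rule, with bars for the SE. Open points mark genes listed at 0 in at least 1 irradiated library; Krt28 is the fall with a value in every library.

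The count of called genes rested on few libraries. It was 4 without nonirradiated replicate 2, 4 without nonirradiated replicate 3, 11 without nonirradiated replicate 4, 20 without irradiated replicate 1, 51 without irradiated replicate 3 and 76 without nonirradiated replicate 1. Without irradiated replicates 1 and 4, which had the highest commonest low read counts, it was 9, a setting chosen after seeing the data. With the muscle index of each library as a covariate, also chosen after seeing the data, it was 0, with 1040 genes at an unadjusted p under 0.05.

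Targets of p53, the transcription factor that responds to DNA damage, were higher as a group. Of the 32 tested members 26 lay above 0, with a mean log2 change of 0.81. Ccng1 (chromosome 11, 40748552 to 40755311), with a log2 change of 1.75 and an adjusted p of 0.00870 in limma, rose over all genes tested, and 11 members rose and 0 fell when adjusted over the list alone. Eda2r had a log2 change of 2.56, Ei24 of 1.39 and Trp53inp1 of 1.25, each with a limma adjusted p between 0.0566 and 0.0644. With edgeR on reads Eda2r (2.55, adjusted p = 0.00460) and Trp53inp1 (1.26, adjusted p = 0.0115) passed, and Ei24 was at 0.66 (adjusted p = 0.375). Cdkn1a (chromosome 17, 29090976 to 29100727), the cell cycle inhibitor p21, was at 76.4 ± 13.9 against 36.1 ± 16.9 FPKM (SD, n = 4 each, limma adjusted p = 0.157), and Mdm2, which degrades p53, at 108 ± 18.8 against 52.7 ± 9.81 FPKM (SD, n = 4 each, limma adjusted p = 0.0978). Bax (log2 change 0.86, adjusted p = 0.718) and Trp53 itself (-1.84, adjusted p = 0.425) did not pass in limma. The list had a camera adjusted p of 4.28e-11 and an adjusted p = 0.0528 with an estimated correlation; the 4 irradiated libraries lay above the 4 nonirradiated ones.

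Genes of the hair shaft and inner root sheath were lower. Of 35 tested members 34 lay below 0, with a mean log2 change of -1.51. Krt28, Krt71 and Tchh fell over all genes tested, and 21 members fell and 0 rose when adjusted over the list alone. Tchh, the trichohyalin of the inner root sheath, went from 1085 ± 190 to 380 ± 118 FPKM and Krt71 from 325 ± 52.6 to 109 ± 32.4 FPKM (SD, n = 4 each). Dlx3, a transcription factor of the hair matrix, had a log2 change of -1.80 (limma adjusted p = 0.0829). The camera adjusted p was 3.89e-15, and the adjusted p = 0.0528 with an estimated correlation.

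Genes of cell division were lower too. All 25 mitosis and G2/M genes lay below 0 with a mean log2 change of -1.33; Mki67 (chromosome 7, 135689784 to 135716361, log2 change -2.08, limma adjusted p = 0.0133) fell over all genes tested, and 10 members fell when adjusted over the list alone. Cdca8 (-2.89), Bub1 (-2.45) and Cenpf (-1.72) did not pass over all genes. Cdca8 and Bub1 were listed at 0 in some irradiated libraries and did not pass with edgeR on reads (adjusted p = 0.838 and 0.783). The list had a camera adjusted p of 4.91e-09 and an adjusted p = 0.0528 with an estimated correlation. Replication-dependent histones had a mean log2 change of -1.74, with 20 of 21 members below 0; Hist1h2bn and Hist2h3b fell, and 9 members fell when adjusted over the list alone. With edgeR on reads neither of these 2 passed (adjusted p = 0.118 and 0.155), and with 0 units in irradiated libraries neither was tested on units. Hist1h2ak (-3.54) and Hist1h1a (-2.05) were next. Their camera adjusted p was 4.17e-09, and the adjusted p = 0.0528 with an estimated correlation; 5 members were listed at 0 in all irradiated libraries, and with these at their bound the median went from -1.58 to -1.31. With edgeR on units, a setting chosen after seeing the data, only 2 histone genes could be tested, and the list did not pass (adjusted p = 0.244). All 29 DNA replication genes lay below 0 with a mean of -1.0 (camera adjusted p = 4.97e-05, adjusted p = 0.202 with an estimated correlation), and 0 fell over all genes and 2 when adjusted over the list alone. Rfc4 (-2.19), Gins1 (-2.94), Tyms (-2.28) and Ccne1 (-1.93) had the smallest p. All were listed at 0 in some irradiated libraries. With edgeR on reads none passed (adjusted p = 0.586, 0.504, 0.853 and 0.989). The DNA replication list was not set against random lists matched on units. Homologous recombination and Fanconi genes had a mean of -0.75 with 17 of 21 members below 0 and 0 called in either count (camera adjusted p = 0.00802, adjusted p = 0.202 with an estimated correlation); the adjusted p was 0.0833 without irradiated replicate 3, 0.0581 after quantile normalization, 0.0547 over the 7 members tested with edgeR on units and 0.304 with the muscle index as a covariate. Xrcc2 (-1.62), Nbn (-0.68), Exo1 (-0.98) and Brca1 (-1.11) led it.

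**Figure D3:**
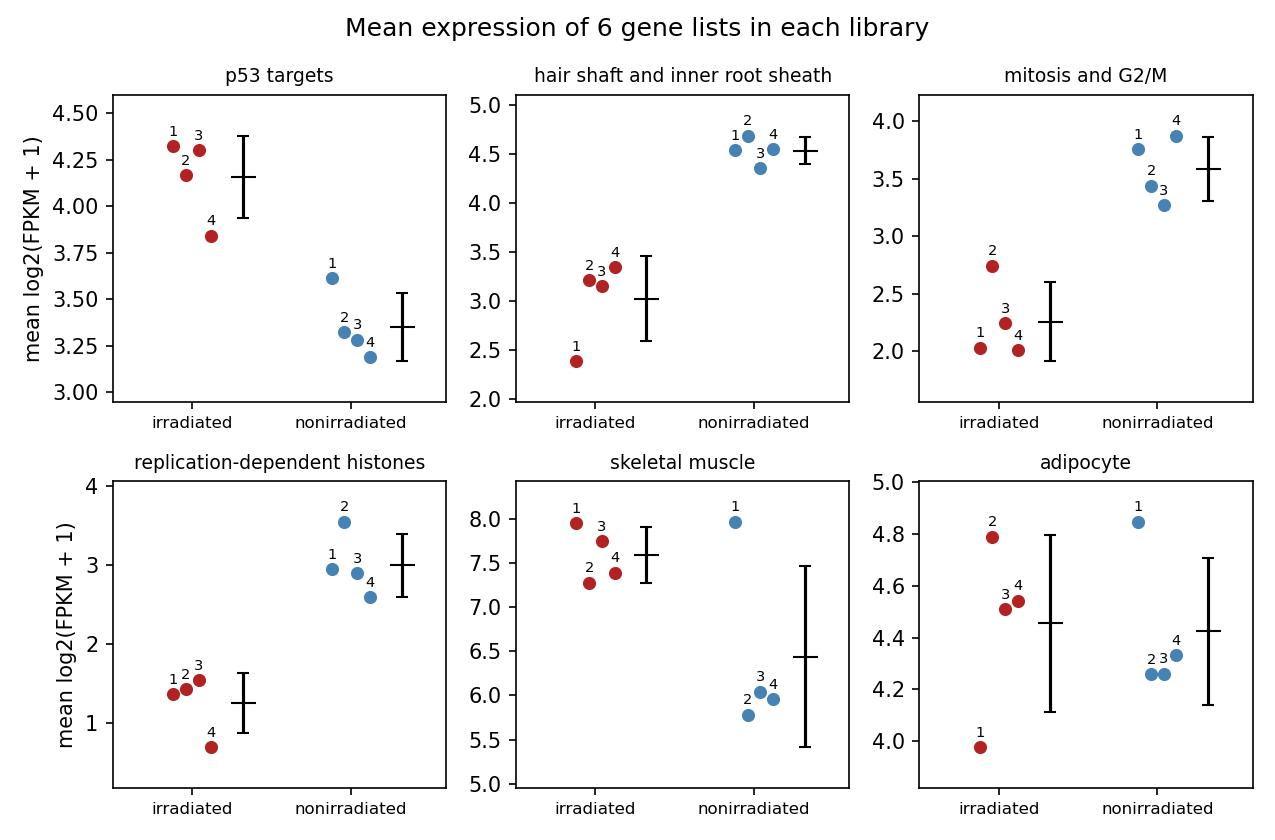
Mean log2(FPKM + 1) of the tested genes of 6 lists (vertical axes) in each of the 4 irradiated (red) and 4 nonirradiated (blue) libraries, numbered by replicate, with the mean and SD of each group in black. The groups do not overlap for p53 targets, hair shaft, mitosis and histone genes; nonirradiated replicate 1 lies at 7.97 for skeletal muscle, with the irradiated libraries between 7.28 and 7.96.

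Skeletal muscle genes were higher, with 15 of 16 members above 0 and a mean log2 change of 1.16. Myh1, a fast myosin heavy chain, rose from 107 ± 104 to 854 ± 185 FPKM (SD, n = 4 each, limma adjusted p = 0.0208), and 7 members rose and 1 fell when adjusted over the list alone. Mb (2.93), Myh2 (2.40) and Mylpf (2.08) did not pass over all genes. Myh4, another fast myosin heavy chain, named after its value was seen, went the other way at -1.83 (limma adjusted p = 0.0912), and with edgeR on reads it passed at -1.87 (adjusted p = 0.0464). The camera adjusted p was 8.64e-08 and the adjusted p = 0.322 with an estimated correlation. The muscle mean was 7.59 ± 0.32 in irradiated and 6.44 ± 1.03 in nonirradiated libraries (SD, n = 4 each, exact permutation p = 0.143), and nonirradiated replicate 1 alone stood at 7.97. Without that library 9 of the 16 members rose. Smooth muscle genes had 8 of 9 members above 0 with a mean of 0.61 (camera adjusted p = 0.00367, adjusted p = 0.184 with an estimated correlation), 0 called over all genes and 2 rises when adjusted over the list alone. Synpo2 (1.38), Des (1.30), Rgs5 (0.83) and Cnn1 (1.11) led it. Without irradiated replicates 1 and 4 its adjusted p was 0.0765. In nonirradiated replicate 1, the library high in skeletal muscle genes, Des was at 114 and Synpo2 at 39.6 FPKM. The other nonirradiated libraries lay between 27.7 and 41.6 FPKM for Des and between 11.8 and 14.8 FPKM for Synpo2. So these 2 rises may share the difference of the skeletal muscle genes. Cnn1 was listed at 0 in most nonirradiated libraries.

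Stress keratins and alarmins had a mean log2 change of 0.87 with 8 of 13 members above 0; S100a8 rose over all genes, and 3 members rose when adjusted over the list alone. With edgeR S100a8 did not pass on reads (adjusted p = 0.0778) and had too few units to be tested. Lcn2 (1.91), Krt16 (2.28) and Krt6b (1.29) did not pass over all genes, and S100a9, the partner of S100a8, was at -0.34 and listed at 0 in 3 irradiated libraries. The camera adjusted p was 0.000923 and the adjusted p = 0.273 with an estimated correlation; it was 0.0759 without irradiated replicate 3, 0.427 over the 4 members tested with edgeR on units and 0.547 over 2 members on thinned units. Basal keratinocyte genes had a mean of 0.39, 9 of 12 members above 0 and 0 called in either count (camera adjusted p = 0.00718, adjusted p = 0.303 with an estimated correlation). That adjusted p was 0.0759 without irradiated replicate 3, 0.680 after quantile normalization, 0.0547 with edgeR on units and 0.378 on thinned units. Itga6 (0.88), Krt14 (0.74) and Krt5 (0.51, but -0.014 after quantile normalization) were named. Krt10, a keratin of differentiating epidermis, was at 417 ± 103 against 239 ± 54.5 FPKM (SD, n = 4 each, limma adjusted p = 0.196).

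Fibrillar collagen and matrix genes had 16 of 20 members above 0 with a mean of 0.50 (camera adjusted p = 0.000332, adjusted p = 0.202 with an estimated correlation) and 0 called in either count. With edgeR on thinned units its adjusted p was 0.372. Col3a1 (0.76), Col6a1 (0.97), Col6a2 (0.82) and Col5a2 (0.60) led it. Sebaceous gland genes had 11 of 14 members above 0, a mean of 0.49 and a median of 0.83; Far2 rose, and 4 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.00129, adjusted p = 0.202 with an estimated correlation). Scd1 (1.06), Krt79 (1.41) and Fads2 (-2.41) followed. Inflammatory cytokines and chemokines had 13 of 16 members above 0, a mean of 0.58 and 0 called in either count (camera adjusted p = 0.0280, adjusted p = 0.277 with an estimated correlation). Its adjusted p was 0.194 without irradiated replicate 3, 0.0624 without nonirradiated replicate 1 and 0.0510 without nonirradiated replicate 3. It was 0.101 with a pseudocount of 0.1, 0.0504 from a mean of 1 FPKM, 0.0675 with the muscle index, 0.154 with edgeR on reads and 0.232 with DESeq2. Csf1 (1.17), Ptgs2 (1.05), Ccl7 (1.54) and Ccl3 (1.14) had the smallest p. Il1b had a log2 change of -0.24 (limma adjusted p = 0.941), which was 0.55 after quantile normalization, and Il6 was listed at 0 in all 8 libraries and was not tested.

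Mitochondrially encoded genes had 9 of 12 members below 0, a mean of -0.20 and a median of -0.88. mt-Nd4 (chromosome M, 10167 to 11544) fell from 16630 ± 1739 to 5334 ± 1025 FPKM and mt-Co2 from 18540 ± 8140 to 5198 ± 950 FPKM (SD, n = 4 each); when adjusted over the list alone 8 fell and 1 rose. mt-Nd5 was at -0.80, and mt-Nd6, on the opposite strand and overlapping it by 14 bp, at 1.54. mt-Co1 was at 19100 FPKM in nonirradiated replicate 4 and under 0.001 FPKM in nonirradiated replicates 2 and 3, which sets the mean of the list. The camera adjusted p was 0.00183 and the adjusted p = 0.0744 with an estimated correlation; after quantile normalization the mean was 0.39 (adjusted p = 0.656), and with no filter the adjusted p was 0.104.

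The other 21 lists did not pass with camera. Adipocyte genes had a mean log2 change of 0.03 with 9 of 16 members above 0 (adjusted p = 0.142), 0 called over all genes and 1 rise when adjusted over the list alone. Fabp4, a fatty acid binding protein of fat cells, was at 1404 ± 374 against 1163 ± 95.5 FPKM (SD, n = 4 each), Adipoq at 0.55, Cfd at 0.95 and Ppara at 0.39 in log2 change, and none passed in limma. Fatty acid uptake and oxidation genes had a mean of 0.13 (adjusted p = 0.0707; 2 rose when adjusted over the list alone; Acadl 1.37), neutrophil genes 0.98 with a median of 0.23 (adjusted p = 0.0779; S100a8 rose), and macrophage and monocyte genes 0.34 (adjusted p = 0.158; Ccr2 1.28). Epidermal barrier genes had a mean of 0.0037 (adjusted p = 0.159; 4 rose and 1 fell when adjusted over the list alone; Calm4 1.53), melanocyte genes -0.58 (adjusted p = 0.223; Mlana fell; Kit 1.32) and T cell genes -0.73 over 4 members (adjusted p = 0.223; Cd3g -1.70). Hair follicle stem cell, Wnt and Shh genes had a mean of -0.46 (adjusted p = 0.281; 1 rose and 2 fell when adjusted over the list alone; Lef1 -1.74), and Langerhans and dendritic cell genes -0.52 (adjusted p = 0.308; Cd209a -1.45).

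Means of the remaining lists were 0.034 for immediate early genes (adjusted p = 0.310; Klf6 0.78), 0.0096 for end joining repair (adjusted p = 0.334; Lig3 1.32; 1 rise adjusted over the list alone) and 0.73 for mast cells over 2 members (adjusted p = 0.363; Kit 1.32). They were 0.067 for the TGF-beta response (adjusted p = 0.476; Cyr61 1.78; 1 rise and 1 fall adjusted over the list alone), -0.30 for endothelial cells (adjusted p = 0.496; Egfl7 -1.90) and -0.33 for oxidative stress defence (adjusted p = 0.611; Mt2 -1.96). For erythrocytes the mean was 0.29 (Slc4a1 1.95), for fibroblasts -0.18 (Mfap5 -1.80), for interferon-stimulated genes -0.028 (Oasl2 1.43) and for cholesterol and fatty acid synthesis -0.20 (Srebf1 1.57; 3 rises and 3 falls adjusted over the list alone), each with an adjusted p of 0.803. Schwann cell and nerve genes had -0.062 (adjusted p = 0.936; Mbp -1.14) and clock genes -0.27 (adjusted p = 0.970; Dbp -1.94). Camera ranked fibroblast, interferon, cholesterol, Schwann cell and clock genes upward although their means lay below 0. The median of interferon genes was 0.023. With members listed at 0 in a whole group at their bound, means moved to -0.33 for melanocyte, -0.47 for T cell and 0.018 for interferon genes. The median of all genes was -0.11, and it was -0.21 after median ratio scaling and -0.011 after quantile normalization.

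Several of these lists passed with camera in other settings. Fatty acid uptake and oxidation genes passed without nonirradiated replicate 1 (mean 0.29, adjusted p = 0.0111) or 4 (0.12, adjusted p = 0.0490), with array weights (adjusted p = 0.0273) and with no filter (adjusted p = 0.0361). They also passed with edgeR on reads (adjusted p = 0.00869), on units (adjusted p = 0.0165) and on thinned units (adjusted p = 0.0291), with DESeq2 (adjusted p = 0.00792), and with a pseudocount of 0.1, where the mean was -0.055 (adjusted p = 0.0437). Epidermal barrier genes passed with edgeR on reads (adjusted p = 0.0295), with DESeq2 (adjusted p = 0.0316) and without irradiated replicate 2 (adjusted p = 0.0445). Neutrophil genes passed after quantile normalization (adjusted p = 0.00388), after median ratio scaling (adjusted p = 0.0114), from a mean of 1 FPKM (adjusted p = 0.0444) and over 2 members with DESeq2 (adjusted p = 0.0316). They also passed without irradiated replicate 2 (adjusted p = 0.0103) and without nonirradiated replicate 1 (adjusted p = 0.0394) or 2 (adjusted p = 0.0261). Macrophage and monocyte genes passed after quantile normalization (adjusted p = 0.0130), without irradiated replicate 1 (adjusted p = 0.0346) and without irradiated replicates 1 and 4 (adjusted p = 0.0152), where immediate early genes passed too (adjusted p = 0.0174). Melanocyte genes passed with array weights (adjusted p = 0.0442) and without irradiated replicate 2 (adjusted p = 0.0475) or 4 (adjusted p = 0.0311). Adipocyte genes passed without irradiated replicate 1 (adjusted p = 0.0349) and with DESeq2 (adjusted p = 0.0493).

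Fry tests whether the genes of a list move, on balance, in one direction, without setting them against other genes. With it, p53 targets, hair shaft genes and histones had an adjusted p of 0.00238 each, mitosis genes 0.00255 and mitochondrially encoded genes 6.485e-05. Homologous recombination and smooth muscle genes had 0.0422 each, collagen genes 0.0467 and DNA replication genes 0.0493. The other lists that passed with camera did not pass with fry: skeletal muscle (adjusted p = 0.168), stress keratins (0.104), basal keratinocyte (0.111), inflammatory cytokine (0.302) and sebaceous gland genes (0.0609). T cell genes (adjusted p = 0.00238, 4 members tested) and hair follicle stem cell, Wnt and Shh genes (0.0177), both lower, passed with fry and not with camera. Their means lay at the 16.1 and 7.72 percentiles of random lists matched on expression. As fry sets no background, it does not remove a general shift to lower values, such as that simulated with no change.

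With edgeR on reads, 11 named genes passed that did not pass in limma, and 12 did not pass that did. The 11 were Eda2r, Trp53inp1, Acadl (adjusted p = 0.0130), Scd1 (0.0173), Dlx3 (0.0195), Lef1 (0.0204), Calm4 (0.0221), Cenpf (0.0259), mt-Nd6 (0.0290), Myh2 (0.0339) and Synpo2 (0.0402). The 12 were S100a8, Hist1h2bn, Hist2h3b, Atat1 (adjusted p = 0.0521), Myoz2 (0.0521), Mrps33 (0.0994), Snrpe (0.103), Mlana (0.105), Mt4 (0.131), Hirip3 (0.198), Myl4 (0.316) and Edf1 (0.507). Of other named genes that passed in neither, some had smaller changes with edgeR on reads than on the FPKM scale and some had larger ones. Lig3 was at 0.24 (adjusted p = 0.926), Srebf1 at 0.47 (adjusted p = 0.912), Oasl2 at 0.70 (adjusted p = 0.7996) and Kit at 0.44 (adjusted p = 0.969). Csf1 was at 0.59 (adjusted p = 0.856), Slc4a1 at 0.73 (adjusted p = 0.953), Ccne1 at -0.88 (adjusted p = 0.989), Egfl7 at -1.17 (adjusted p = 0.953), Trp53 at -0.46 (adjusted p = 0.989) and Adipoq at 0.36 (adjusted p = 0.925). The larger ones were Exo1 at -4.22 (adjusted p = 0.513), Rfc4 at -3.80 (adjusted p = 0.586), Cnn1 at 3.42 (adjusted p = 0.771), Xrcc2 at -3.03 (adjusted p = 0.757), Cd209a at -2.77 (adjusted p = 0.807) and Ccl7 at 2.42 (adjusted p = 0.865). So were Ptgs2 at 1.63 (adjusted p = 0.553), Bax at 1.36 (adjusted p = 0.949) and Ppara at 1.1 (adjusted p = 0.975), and Il1b was at 1.51 (adjusted p = 0.951) against -0.24 in limma.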

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

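Except for the splits of the samples for the counts of genes and lists, the tests below were chosen after the results they bear on had been seen. Of 276 sets of 4 libraries looked at with Dixon's test, 26 had 1 library far from the rest. The nominal rate for independent, normal values gives about 13.8. These sets are neither, as lists share members with named genes and many genes are listed at 0, so the excess is not measured against chance. The flags fell on irradiated replicate 3 in 9 cases and on irradiated replicate 2 and nonirradiated replicate 1 in 6 cases each. Irradiated replicate 3 had the most units of its group (332687), and flags such as Edf1, Gins1, Rfc4 and Cd3g are genes at 0 in its other libraries. The deposited count columns, which the limma test on FPKM does not use, held a commonest low read count of 51.5 on average in irradiated libraries, above the 9.94 of the nonirradiated libraries.

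Fewer genes were listed above 0 in irradiated libraries, and their commonest low read count was higher. A candidate explanation is that fewer distinct fragments were copied more often in these libraries: with every library thinned to 75894 units, 7.78% of the difference in genes detected was left, a mean difference of -227 genes (exact two-sided permutation p = 0.543). So among genes that 75894 units can reach, the groups differed little. Weakly expressed genes drop out of every library at that depth, where the nonirradiated mean goes from 13212 to 9292 genes. A loss of such genes in irradiated skin therefore cannot be told apart from fewer fragments. The candidate explanation rests on reading the peak of low read counts as 1 fragment, which no value here checks. Whether fewer fragments came from the RNA or from the library preparation stays open.

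Hair shaft, mitosis and histone genes fell together. The idea that few fragments lower weakly expressed genes alike is argued against for hair shaft and mitosis genes. With members listed at 0 at their bound, their means lay below the lowest of 10000 random lists matched on expression and units, at -0.85 and -0.43 from it. With edgeR on units, hair shaft (adjusted p = 2.34e-21) and mitosis genes (adjusted p = 3.1e-11) passed. Only 20 of 35 hair shaft and 10 of 25 mitosis members could be tested on units, so that result does not cover the rest. The histone mean also lay below, at -0.42 from the lowest, but 5 members were listed at 0 in all irradiated libraries. On units 2 histone genes could be tested and the list did not pass (adjusted p = 0.244), so the idea stays open for them. Random lists hold unrelated genes, so a technical factor shared by the genes of a list was not tested. Fewer follicles in the irradiated pieces cannot be decided from these lists. The sebaceous gland list, whose glands sit on follicles, had a median of 0.83. That lies 2.16 above the mildest mean of the 3 lists (-1.33), more than the SD of 1.27 over its genes. This comparison assumes that glands kept their expression, while Far2 of that list rose by 2.52. The hair follicle stem cell, Wnt and Shh list went the other way, with a mean of -0.46 and 15 of 21 members below 0. Its 4 irradiated libraries all lay below the nonirradiated ones. A different stage of the hair cycle at the irradiated areas cannot be told apart from irradiation itself, which stays open too, because the groups are fully separate (highest irradiated minus lowest nonirradiated hair index -1.01) and area and dose coincide.

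Skeletal muscle genes were higher in irradiated libraries and in nonirradiated replicate 1, which at 7.97 stood apart from 5.78 to 6.04 in the other nonirradiated libraries. More muscle in the cut pieces is a candidate explanation for the higher genes, since this nonirradiated library stood just above the highest irradiated one (7.96). Myh4, a muscle gene, was lower in every irradiated library (highest irradiated minus lowest nonirradiated -0.79 in log2), which more muscle of the same kind would not give. Myh4 was picked after its value was seen, so it is no separate test of muscle share. For genes of immature or injured muscle (18 listed after the fit was seen, of which 5 already seen as high were left out and 10 tested), the mean change was 1.20, and 0.77 with a standard error of 0.45 with the muscle index as a covariate. Only 1 nonirradiated library has an index as high as the irradiated ones, so for these genes muscle share and a response of muscle to irradiation cannot be told apart.

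All splits of the 8 libraries into 4 and 4 number 35, a split and its mirror counted as 1. The real split gave 33 genes and the highest other split 2, so that 1 of 35 splits gave as many. For the larger side it was 17 genes against 2, again 1 of 35. That share of 0.0286 is the smallest this design allows and is not adjusted for the several values tested by splits. For lists past the threshold with the preset correlation, the real split gave 14 and the highest other 15, so that 2 of 35 splits gave as many and chance cannot be excluded for that count. That other split set irradiated replicates 1, 2 and 3 and nonirradiated replicate 1 against the rest. The size of the mean change was the largest of all splits for p53 targets (0.81, highest other 0.69), mitosis (1.33, highest other 1.06) and hair shaft (1.51, highest other 1.00), each in 1 of 35. In the exact permutation tests of library means these lists had p = 0.0286 each, with an adjusted p = 0.0686 over 12 measures. For adipocyte genes 34 of 35 splits gave a mean as large as 0.03, with 0.47 as the highest other.

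Other libraries that stood apart are given as log2(FPKM + 1). Nonirradiated replicate 1 was the highest of its group for the means of cholesterol and fatty acid synthesis (4.29) and adipocyte genes (4.85), and for Acadl (6.53), Myh2 (5.53) and Rfc4 (2.90). Irradiated replicate 3 was the highest for Cd3g (1.71), Edf1 (2.64), Gins1 (1.97), Hist1h2ak (2.44), Il1b (4.19), Mrps33 (0.15), Rfc4 (1.33) and Xrcc2 (1.00), and the lowest for Adipoq (4.32). Irradiated replicate 2 was the highest for Ccne1 (2.51), Cenpf (3.17), Exo1 (0.37), Fabp4 (10.9) and Hist1h2bn (0.60) and the lowest for Col6a2 (3.78). Irradiated replicate 1 was the highest for Cd209a (1.36) and irradiated replicate 4 the lowest for Mt2 (0). Nonirradiated replicate 3 was the highest for Cnn1 (0.67), and nonirradiated replicate 4 the lowest for Krt14 (7.61) and Trp53 (3.62).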

How the results depend on the processing

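The fits with edgeR or DESeq2, with units, without irradiated replicates 1 and 4 and with the muscle index were chosen after seeing the data. p53 targets (0.58 to 1.13), mitosis (-2.13 to -1.09) and hair shaft genes (-2.12 to -1.30) kept their direction in the alternatives run and passed with camera at the preset correlation in each. With the correlation estimated from the data, means of 0.81, -1.33 and -1.51 each had an adjusted p of 0.0528. The cause of the changes below was not tested, except that leaving out libraries leaves fewer samples. The settings foreseen for raw counts, DESeq2 in place of edgeR and no count filter, were not run in that form, as the deposited counts are scaled. A minimum log2 change of 1 left 33 calls (16 higher, 17 lower). Units limit how many genes can be tested with edgeR: 5857 in units and 1708 in thinned units.

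The 33 calls (16 higher, 17 lower) became 102 (59 and 43) with array weights, 92 (50 and 42) with edgeR on reads, 509 (292 and 217) with edgeR on units, 167 (94 and 73) on thinned units and 745 (392 and 353) with DESeq2. They became 9 (3 and 6) without irradiated replicates 1 and 4, and 24 (5 and 19) with no trend or robust moderation. With the muscle index as a covariate limma called 0 genes (0 higher, 0 lower), with 1040 at an unadjusted p under 0.05. Median ratio scaling gave 19 higher and 26 lower, a pseudocount of 0.1 gave 14 and 23, and quantile normalization 23 and 22. Of the 33, 19 were shared with edgeR on reads and 32 with DESeq2. Leaving out 1 library gave 4 to 76 calls, 2 to 59 higher and 1 to 31 lower.

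The deviations gave no clear sign of pairing by replicate number: same-numbered libraries correlated at -0.013 to 0.09, and 1 of 4 correlated best with its own number. With so few and variable libraries this cannot show that they are unpaired. With the replicate block 16 genes were called (11 higher, 5 lower), and fatty acid oxidation genes passed (adjusted p = 0.0390). With the block and an estimated correlation, p53 targets, mitosis and hair shaft genes had an adjusted p of 0.176 each.

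Values whose sign turned lay near 0 or did not pass in the main test, except mitochondrially encoded genes. With a pseudocount of 0.1 the means were end joining -0.23, barrier -0.15, fatty acid oxidation -0.055, TGF-beta -0.27, immediate early -0.28, adipocyte -0.21 and erythrocyte -0.31, and Ppara was -0.12. With no filter, end joining was -0.041, barrier -0.00088 and mast cell -0.050. From 1 FPKM, interferon was 0.050, barrier -0.012 and immediate early -0.016. With median ratio scaling, end joining was -0.096, barrier -0.10, TGF-beta -0.030, immediate early -0.054 and adipocyte -0.071. With quantile normalization, interferon was 0.25, barrier -0.0087, mitochondrially encoded 0.39, Schwann cell 0.19, Fabp4 -0.29, Il1b 0.55 and Krt5 -0.014. With array weights, interferon was 0.18, mitochondrially encoded 0.048, fibroblast 0.059 and Il1b 0.23.

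With the muscle index, end joining was -0.21, barrier -0.35, fatty acid oxidation -0.21, TGF-beta -0.10, immediate early -0.23, adipocyte -0.16, Ccl3 -0.45 and Ppara -0.58. Without irradiated replicates 1 and 4, interferon was 0.30, fibroblast 0.077, endothelial 0.043, Schwann cell 0.050, erythrocyte -0.035 and Il1b 0.88. With edgeR on reads, end joining was -0.16, interferon 0.12, TGF-beta -0.037, Schwann cell 0.16 and Il1b 1.51; with DESeq2, end joining -0.25, interferon 0.15, Schwann cell 0.21 and Il1b 1.52, and adipocyte genes passed at 0.13 (adjusted p = 0.0493). On units, end joining was -0.061, interferon 0.068 and fibroblast 0.036; on thinned units, oxidative stress 0.018, hair follicle stem cell 0.076, TGF-beta -0.0030 and fibroblast 0.20.

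Leaving out 1 library gave ranges of -0.081 to 0.19 for adipocyte (passing at 0.19 without irradiated replicate 1), -0.076 to 0.14 for end joining, -0.14 to 0.18 for interferon, -0.22 to 0.22 for barrier, -0.11 to 0.34 for TGF-beta, -0.14 to 0.30 for immediate early, -0.29 to 0.023 for fibroblast, -0.27 to 0.085 for Schwann cell and -0.36 to 0.72 for erythrocyte genes. For Il1b it gave -1.26 to 0.13 and for Ppara -0.31 to 0.86. Only lists and named genes whose sign turned are given here, so the size of other means may move as well.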

Other observations

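Pathways of the KEGG annotation in the deposited table were tested after the lists had been seen, as an exploration. Of 275 pathways with 10 to 300 tested genes, 23 passed with camera at the preset correlation and 0 with an estimated correlation, with 56 at an unadjusted p under 0.05. Proteasome genes had a mean log2 change of 0.24 with 31 of 42 above 0 (adjusted p = 0.0106), and genes of the citrate cycle 0.39 with 23 of 28 above 0 (adjusted p = 0.00431). With the muscle index as a covariate the proteasome and citrate cycle means were 0.076 and 0.11. The pathway named basal cell carcinoma, which holds Wnt and Hedgehog signalling genes, had a mean of -0.63 with 32 of 42 below 0 (adjusted p = 0.0244). No pathway named for Wnt or Hedgehog signalling itself was among the 23 that passed. The list of hair follicle stem cell, Wnt and Shh genes had not passed with camera either. The p53 signaling pathway had a mean of 0.03 with 33 genes above and 29 below 0 (adjusted p = 0.206), the cell cycle -0.33 (adjusted p = 0.421), homologous recombination -0.44 (adjusted p = 0.410) and the Fanconi anemia pathway -0.37 (adjusted p = 0.318). These 4 did not pass, and the DNA replication pathway did, with a mean of -0.72 and 27 of 35 below 0 (adjusted p = 0.0357). Each pathway with values given here had an adjusted p = 0.982 with an estimated correlation.

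Gdf15, a p53 target that encodes a secreted stress cytokine, was named after its values were seen. It was listed at 0 in the 4 nonirradiated libraries and in irradiated replicate 4, with 3.86 ± 3.29 FPKM in the irradiated libraries (SD, n = 4). From 5 units, its irradiated rate was 8.18 times a floor of 3 units for the nonirradiated group (limma adjusted p = 0.250). That ratio leaves out the counting error of the 5 units, so it is not a lower limit of the change.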
